A study of Mus musculus with 12 samples.

How the data were processed

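Messenger RNA from purified CD8 T cells of mixed bone marrow chimeras was sequenced in 12 libraries: scurfy or wild type, unstimulated or given SIINFEKL peptide for 6 h, 3 libraries each. Per the labels' protocols, polyadenylated RNA was reverse transcribed from indexed oligo-dT primers, amplified linearly by in vitro transcription, fragmented and sequenced on a NextSeq 500. Such oligo-dT priming places the index at the 3' end of the transcript. Per the submitters' processing notes, reads passed through Trim Galore 0.4.4, STAR 2.6 and featureCounts with build NCBIM37, and edgeR and DESeq2 are named without a role. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain.

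Groups and replicate numbers were taken from the sample titles. Of the 2 deposited tables, 1 was used: the other holds the same values and also names its columns after the 6 unstimulated libraries, so the stimulated libraries, the 4 comparisons that need them and their alternatives were not analysed here. The deposited value of a gene in a library is a signal, a read count divided by a size factor per library, as read from the values and the DESeq2-style columns per the file headers. Within each library 100% of nonzero values came out as whole multiples of 1 read, within 0.01 read, which gave the recovered reads and the depth. Per the file headers, the deposited table also gives the authors' log2 fold change with its standard error, a test score (their ratio), and a p-value with its adjusted form. The authors' deposited comparison was used only for counts of calls and 1 fold change. The table has 11581 genes, the smallest mean normalized count being 7.10. A filter on low genes was applied before deposit by a rule not given in the sources used here, so a gene without a row says nothing about its level. Of the gene IDs, 11571 matched GENCODE M21, which also gave chromosomes, exonic lengths and GC contents on GRCm38. No start or end positions are given, because the submitters' build differs.

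The test planned for read counts was edgeR's quasi-likelihood test. Since the values were normalized, the test planned for that case was used: limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trend of variance on mean, robust empirical Bayes moderation (4 residual and 10.7 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05, over the 6 libraries with no covariate. Log2 fold changes are scurfy minus wild type on that scale, which understates changes of low genes. Unless another tool is named, calls and counts of genes that rose, fell or passed are those of limma. A mean ± SD is over deposited normalized counts of 3 libraries. At this depth 3 reads correspond to 1.45 to 3.99 normalized counts. The script was also tested on simulated data with changed genes. No 2 libraries of a group agreed within sampling noise: their counts differed by 7.65 to 39.2 times the variance that sampling gives.

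Genes were named by a rule fixed before the data were examined. It takes Foxp3 first, then, among genes past the threshold with a mean of at least 5 CPM, a named symbol and no overlap between groups, the 10 largest rises and 10 largest falls. From each of 29 gene lists it takes up to 4 members past the threshold with the smallest p, or the member with the smallest p. The lists, also fixed before the data were examined, covered T cell identity and state, activation, effector and inhibitory genes, metabolism, ribosomes, cell cycle, signalling, stress, TGF-beta, the genes flanking Foxp3, sex-linked and mitochondrially encoded genes, and markers of CD4 T, B, myeloid, natural killer and erythroid cells. The 24 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. With the estimated correlation no list kept an adjusted p under 0.05. Directional fry tests whether the genes of a list move one way without comparing them with other genes. It gave an adjusted p of 0.0353 for oxidative phosphorylation and for cytosolic ribosomal proteins, and 0.000539 for B cell markers. No other list passed it. Mixed fry, also planned, tests whether the genes of a list change in either direction. Its adjusted p was under 0.05 for most lists. The exceptions were T cell receptor early activation, cytokines and chemokines, glycolysis, cell cycle, interferon response and mitochondrially encoded genes.

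Explanations were tested for 3 patterns and for the grouping of the libraries, with criteria written down before each result was seen except where said here. The trend with GC content was planned and run for both lists, then taken out of the weighing after its results were seen, to keep the explanations weighed for each list to 3. Its values are given with the others. The trend with mean expression fitted without ribosomal protein genes was added after the planned version had been seen. The interval on the Slc15a2 percentile was added after the percentile had been seen, and changed the outcome from excluding a chromosome segment to leaving it open. An explanation of the B cell markers by admixed B cells was written after the fold changes had been seen and dropped after the marker values had been read. Its criterion, every marker lower in scurfy, only restated the pattern and was met by all 8 markers.

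Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, TMM, upper-quartile, library-size and recomputed size-factor scaling, at least 20 reads in at least 3 libraries, DESeq2 1.42.0 and limma-voom on the recovered reads, the replicate number as a block, and each library left out in turn. A planned filter at a mean of 1 removes no gene and gave no separate result. Chosen after seeing the data were edgeR 4.0.16's quasi-likelihood test on the recovered reads, a filter at a mean of 50, and the removal of a loess trend (span 0.5) of fold change on exonic length or on GC content. Figures were drawn with matplotlib 3.10.9 from the tables made with pandas 2.3.3.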

Results

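RNA sequencing was used to ask how CD8 T cells differ when they carry the scurfy mutation, a loss-of-function mutation of Foxp3, the transcription factor best known from regulatory T cells. The cells were OT-1 cells, whose transgenic T cell receptor recognises the SIINFEKL peptide of ovalbumin, taken from mice reconstituted with mixed bone marrow. The series holds 12 samples in 4 groups, scurfy or wild type, unstimulated or given peptide for 6 h, with 3 libraries in each group. The comparison made here is between the 3 unstimulated scurfy and the 3 unstimulated wild-type libraries. The stimulated libraries were not analysed here, because both deposited tables hold the same values under the column names of the 6 unstimulated libraries. The scurfy libraries held 10091477, 10189535 and 10498525 reads over the 11581 genes of the table. The wild-type libraries held 8852518, 23149523 and 12841455. The labels do not say whether libraries came from separate mice, so p-values measure the spread between these samples, which may be technical.

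Foxp3 itself has no row among the 11581 genes and was not analysed here, so the genotype labels were not checked against the transcript of the mutated gene. In unstimulated scurfy cells the most strongly changed transcript by p was Slc15a2, which encodes a proton-coupled peptide transporter. It fell from 550 ± 24.7 normalized counts in wild type to 59.3 ± 28.8 in scurfy (SD, n = 3 each), a log2 fold change of -3.33. Of 48 nuclear-encoded genes of oxidative phosphorylation 11 rose and 37 did not pass, with Cox7a2 (log2 fold change 1.30), Cox6c (1.18), Uqcrh (1.03) and Cox6b1 (0.96) among those that rose. The list as a whole did not keep its call with an estimated correlation (adjusted p = 0.241) or with a length trend removed (adjusted p = 0.172). Dapl1, a transcript abundant in naive CD8 T cells, rose 2.27-fold to 7369 ± 675 normalized counts from 3276 ± 588, whereas S1pr1, the receptor that guides T cell exit from lymphoid organs, fell by 0.76 on the log2 scale. The costimulatory receptor Cd28 fell by 0.67 on the log2 scale and the T cell receptor component Cd3d rose by 0.76. No tested member of the lists of T cell receptor-induced genes, cytokines or cell cycle genes passed the threshold in limma. Only 11 of 23 planned cytokine and chemokine genes and 17 of 30 planned cell cycle genes had a row.

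Across the table, 518 of 11581 genes (4.47%) passed an adjusted p of 0.05 in limma, 246 higher and 272 lower in scurfy libraries. Most differences were modest: the median fold was 1.72 among the genes that rose and 1.64 among those that fell, and 123 genes differed by more than 2-fold, 75 of them higher. The values of the groups did not overlap for 27.1% of all genes, against the 10% that chance gives with 3 against 3. On library size alone, without the authors' scaling, 929 genes passed, 168 higher and 761 lower, and the median log2 fold change of all genes was lower by 0.14. The count was 113 without wild-type library 3, 215 without wild-type library 2, 306 without wild-type library 1, 221 without scurfy library 2 and 230 without scurfy library 3. Scurfy library 3 and wild-type library 3 also lay farthest apart on the first principal component, at -31.4 and 24.4, which held 46.4% of the variance and separated the genotypes.

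Among genes with a mean of at least 5 CPM, the 10 with the largest rise included Mtus2, a microtubule-associated protein gene (ENSMUSG00000029651, chromosome 5 in GENCODE M21). It was at 128 ± 23.9 normalized counts in scurfy and 26.8 ± 10.7 in wild type (log2 fold change 2.28, SE 0.36, limma adjusted p = 0.00551). Trnp1 rose from 77.3 ± 24.2 to 287 ± 50.2. Slirp, which binds mitochondrial messenger RNA, rose from 68.2 ± 8.66 to 239 ± 63.0, and Nop10, a component of small nucleolar ribonucleoproteins, from 243 ± 62.3 to 789 ± 310. Lcn4 rose by 2.15 on the log2 scale. The processed pseudogene ENSMUSG00000100865 (chromosome 17 in GENCODE M21) rose by 1.93, an uncertain value because such copies share reads with their parent gene. Rell1 rose by 1.88, Lsm5 by 1.77, Snhg9, which is annotated as antisense to another gene, by 1.65 and Lyrm4 by 1.53. Their calls ended with 1 library left out, any of 4 for Rell1 and Lsm5, 3 for Lyrm4 and 2 for Snhg9. Without wild-type library 3 none of these 4 genes passed. The highest adjusted p after leaving out one library was 0.0598 for Rell1 without scurfy library 3, 0.0841 for Lsm5 without wild-type library 3, 0.0672 for Snhg9 without scurfy library 3 and 0.0609 for Lyrm4 without scurfy library 2.

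The largest falls followed Slc15a2 (ENSMUSG00000022899, chromosome 16 in GENCODE M21, SE 0.31, limma adjusted p = 0.000328), which kept its call whichever library was left out, with an adjusted p of at most 0.00458. Zfp36l1, which promotes decay of AU-rich messenger RNA, fell from 381 ± 95.6 to 152 ± 46.2 normalized counts. The reader of methylated RNA Ythdf2 fell from 227 ± 54.8 to 73.1 ± 42.4, and the histone demethylase Kdm1b from 146 ± 32.7 to 51.2 ± 25.2. Taf15 and Taf5, of the TFIID family of initiation factors, fell by 1.37 and 1.35 on the log2 scale, and the Ets factor Fli1 fell by 1.28. Gmcl1 fell by 1.59, Fbxo11, a subunit of a ubiquitin ligase, by 1.26, and the poly(A) polymerase Papd4 by 1.25. Without wild-type library 3 none of these other 9 genes passed, with adjusted p of 0.0618 for Gmcl1, 0.0534 for Zfp36l1, 0.0587 for Fbxo11, 0.0547 for Taf5, 0.105 for Papd4 and for Kdm1b and 0.115 for Taf15. Ythdf2 reached 0.133 and Fli1 0.0727 without wild-type library 1.

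**Figure D1:**
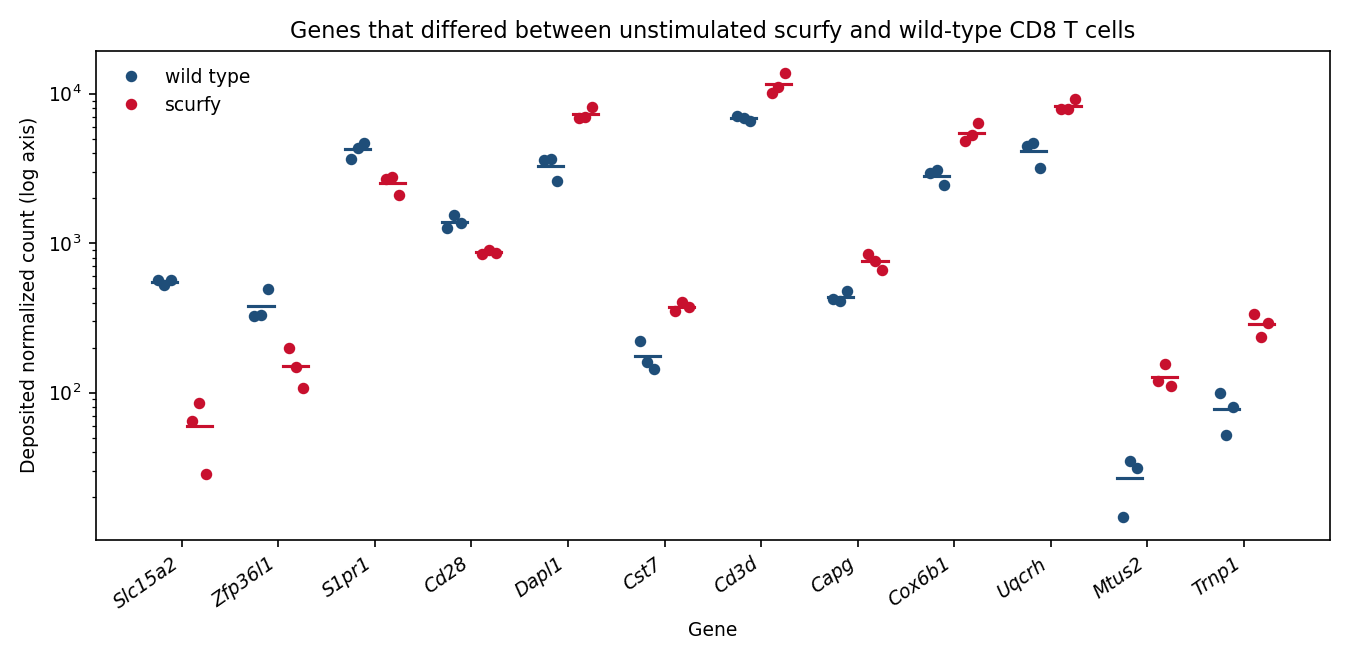
Deposited normalized counts (log axis) of 12 genes in the 3 wild-type (blue) and 3 scurfy (red) unstimulated libraries, 1 point per library, with a line at each group mean. Slc15a2 lies between 28.4 and 85.4 in the scurfy libraries and between 522 and 565 in the wild-type libraries, and no gene's groups overlap.

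Genes of oxidative phosphorylation were shifted upward in scurfy libraries. Of 48 nuclear-encoded members, 11 rose, none fell and 37 did not pass, and adjusted over the list alone 22 rose and 1 fell. Cox7a2 rose from 915 ± 202 to 2258 ± 539 normalized counts, and Uqcrh from 4109 ± 799 to 8296 ± 781. Cox6c rose from 1055.0 ± 132 to 2460 ± 813 and Cox6b1 from 2819 ± 331 to 5495 ± 767 (limma adjusted p of the 4 from 0.00188 to 0.00632). All 4 kept their calls whichever library was left out. The median log2 fold change was 0.27, and camera placed the list above the other genes with adjusted p = 1.08e-07, though the adjusted p was 0.241 with an estimated correlation. These genes are short, with a median exonic length of 1128.5 bases against 2952 over all genes, and short genes in general were higher in scurfy libraries. The 6 mitochondrially encoded members tested had a median of -0.21, and none passed (mt-Nd4 at -0.55, adjusted p = 0.0684). That median was 0.07 without scurfy library 3, -0.41 without scurfy library 1 and 0.06 with the GC trend removed. Of 18 genes of the TCA cycle, Sucla2 fell by 0.58 and none rose in limma (adjusted over the list alone 2 rose and 1 fell). Leaving out any 1 of the 6 libraries ended the Sucla2 call, with adjusted p up to 0.13. DESeq2 on recovered reads called 2 of the 18 higher and 1 lower. None of 17 glycolysis genes passed, Pfkl being closest at 0.64 with adjusted p = 0.0648.

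Cytosolic ribosomal proteins moved in the same direction. Of 34 members, 7 rose, none fell and 27 did not pass, and adjusted over the list alone 16 rose. Rps24 rose by 1.04 on the log2 scale, Rpl32 by 0.69 and Rps6 by 0.48, each of them losing its call without at least 1 library. Rps24 had an adjusted p of 0.0806 and Rpl32 of 0.0547 without wild-type library 3, and Rps6 of 0.0701 without wild-type library 1. The median was 0.35 and camera gave an adjusted p of 6.98e-10, with an adjusted p of 0.241 with an estimated correlation. Ribosomal protein genes have many near-identical pseudogenes that can share reads, and their median exonic length was 1055.5 bases, so the length difference between the groups runs with this list too. Of 24 ribosome biogenesis genes, Nhp2 rose by 0.47 (adjusted p = 0.0683 without wild-type library 2), and adjusted over the list alone 1 rose and 1 fell. With the length trend removed Nhp2 was at 0.27 (adjusted p = 0.157), Rps6 at 0.23 (0.233) and Rpl32 at 0.47 (0.0852), so their calls ended. Rps24 kept its call under that correction (1.00, adjusted p = 0.0316).

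**Figure D2:**
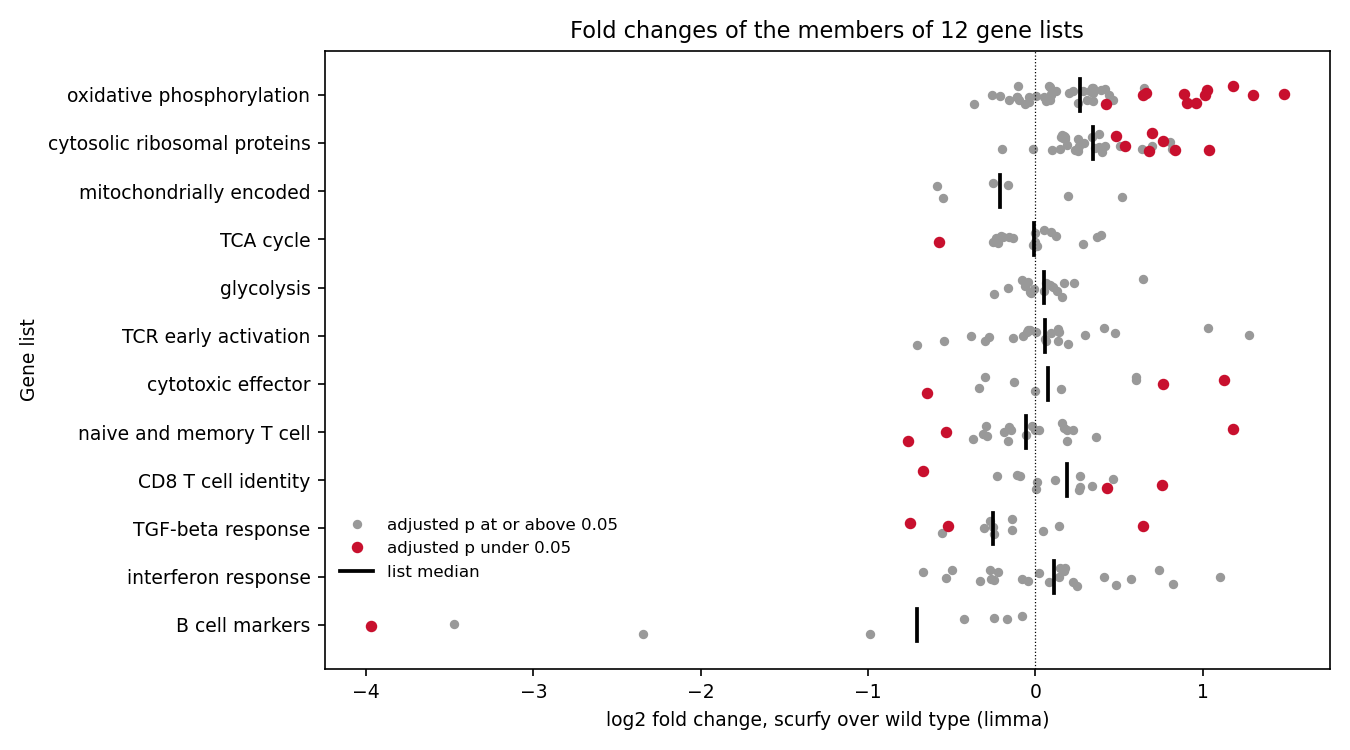
Log2 fold changes, scurfy over wild type, of the members of 12 gene lists, with the members past an adjusted p of 0.05 in red, the others in grey and a black bar at each list's median. Oxidative phosphorylation (median 0.27) and cytosolic ribosomal proteins (0.35) lie to the right of 0 and B cell markers (-0.71) to the left.

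Gene length divided the comparison as a whole. The 1379 genes with under 1000 bases of exon had a median log2 fold change of 0.32, and 125 of them rose while 8 fell, whereas the 3840 genes with over 4000 bases had a median of -0.08, with 14 rising and 122 falling. Across genes, which are not independent replicates, Spearman's correlation between length and log2 fold change was -0.27. A value per library was taken over 718 of the short and 3281 of the long genes. The median deviation of short genes minus that of long genes was 0.18, 0.24 and 0.17 in scurfy libraries 1 to 3 and -0.11, -0.23 and -0.28 in wild-type libraries 1 to 3. The difference was 0.40 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). With a smooth length trend taken out, 245 genes passed, 82 higher and 163 lower, of which 227 were among the 518.

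**Figure D3:**
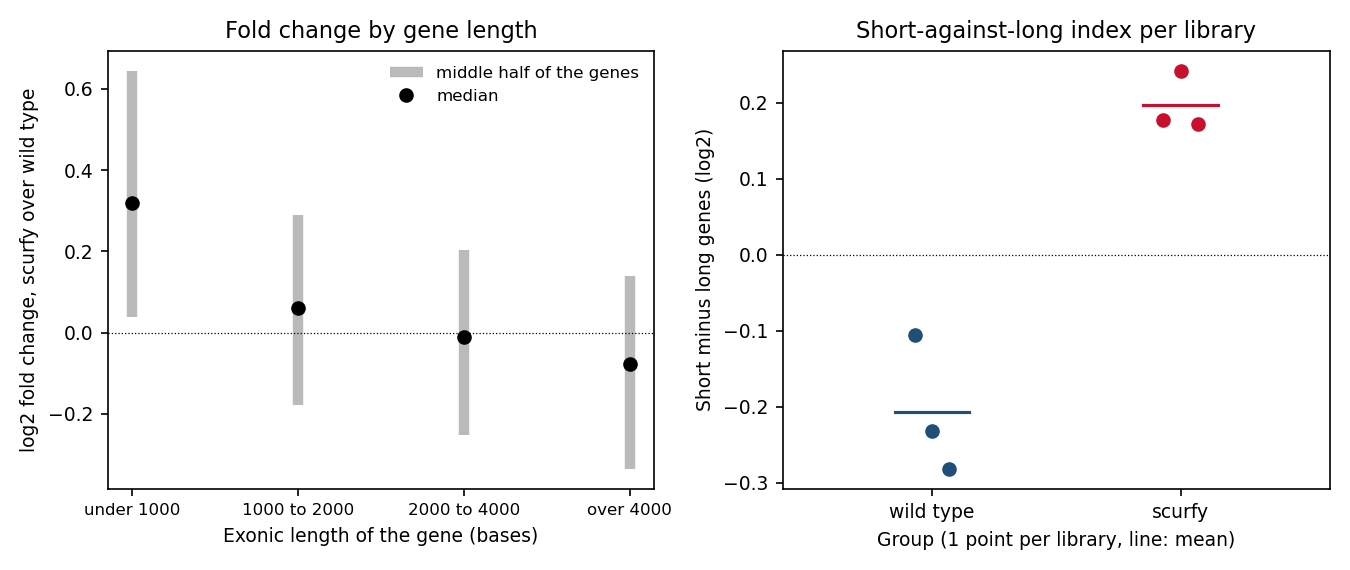
Left, log2 fold change, scurfy over wild type, in 4 classes of exonic length, with the median as a point and the middle 50% of genes as a bar. Right, the median deviation of 718 genes under 1000 bases minus that of 3281 genes over 4000 bases (log2), 1 point per library with a line at the group mean: the scurfy libraries lie between 0.17 and 0.24 and the wild-type libraries between -0.28 and -0.11.

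T cell identity and state genes changed individually and in both directions. In the list of 14 CD8 T cell identity genes, Cd3d rose from 6837 ± 281 to 11635 ± 1898 normalized counts, the adhesion receptor Cd2 rose by 0.43, and Cd28 fell from 1391 ± 146 to 870 ± 24.4. The other 11 did not pass, Cd8a among them at 0.12 (adjusted over the list alone 3 rose and 1 fell, camera adjusted p = 0.388). In limma, of 21 naive and memory genes Dapl1 rose and S1pr1 and Il6ra (-0.53) fell, while the naive-cell factors Lef1 (-0.37) and Klf2 (-0.31) did not pass. Adjusted over the list alone 1 rose and 5 fell (camera adjusted p = 0.724). DESeq2 on recovered reads called 1 of the list higher and 4 lower, Lef1 among them. Ly6c2 rose by 0.90 in the list of 14 memory-phenotype genes, where Cd44 was at -1.31 with adjusted p = 0.0933, and adjusted over the list alone that was 1 gene as well (camera adjusted p = 0.873). Of 24 planned cytotoxic genes 10 had a row, Gzmb and Ifng not among them. Of these 10, Cst7, an inhibitor of granule cathepsins, rose from 175 ± 40.7 to 376 ± 25.6, and the granule membrane protein Nkg7 by 0.76. The receptor subunit Klrd1 fell by 0.65, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.724). The inhibitory receptor Btla rose by 0.91 among 9 inhibitory genes, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.724). With the length trend removed Nkg7 was at 0.52 and lost its call (adjusted p = 0.0662). So did Cd2 at 0.26 (0.201), Ly6c2 at 0.65 (0.1145) and Il6ra at -0.43 (0.0877). The other genes called in this paragraph kept their calls under that correction. Leaving out any 1 of the 6 libraries ended the call of Cd2, any of 5 that of Il6ra and Ly6c2, and any of 4 that of Klrd1 and Btla. Without wild-type library 3 none of these passed. The highest limma adjusted p was 0.129 for Cd2, 0.0875 for Il6ra, 0.0903 for Ly6c2 and 0.124 for Klrd1, each without wild-type library 3. For Btla it was 0.0852 without scurfy library 3.

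Of 22 planned genes associated with regulatory T cells 12 had a row. Of these 12, Capg, an actin-capping protein, rose from 435 ± 35.5 to 755 ± 93.7 normalized counts. The other 11 did not pass, among them Tnfrsf18 (0.35), Nrp1 (-0.84) and Ikzf2 (-0.57), with 1 gene adjusted over the list alone as well (camera adjusted p = 0.724). In the TGF-beta list of 12, the inhibitory factor Smad7 fell by 0.52 and the co-repressor Tgif1 by 0.75, and Tgfb1, the cytokine itself, rose by 0.64, the same counts adjusted over the list alone (camera adjusted p = 0.134). Stim2, a sensor of calcium in the endoplasmic reticulum, fell from 286 ± 7.44 to 159 ± 3.76 as the one call among 28 calcium and NFAT genes. The chaperone Hspa5 fell by 0.69 as limma's one call among 16 heat shock genes, both also 1 gene adjusted over the list alone (camera adjusted p = 0.724 and 0.772). Voom called 1 heat shock gene higher and 1 lower. Without wild-type library 3, adjusted p was 0.12 for Tgfb1, 0.0645 for Stim2 and 0.125 for Hspa5, Smad7 reached 0.0957 without wild-type library 2 and Tgif1 0.0869 without scurfy library 3. The call ended with any of 5 libraries left out for Tgfb1 and Tgif1, 4 for Hspa5 and Smad7 and 2 for Stim2.

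In 10 lists with 173 distinct genes, limma called none, over all genes or, except mitochondrially encoded mt-Nd4, adjusted over the list alone. Of these genes 20 had an unadjusted p under 0.05, DESeq2 on recovered reads called 8, and edgeR and voom called none. They were the mitochondrially encoded and glycolysis lists, T cell receptor early activation (23 genes, with Junb at -0.71 and adjusted p = 0.0697), cytokines and chemokines (11, with Ccl3 at -1.24), cell cycle (17, with Pcna at -0.41), and interferon response (24, with Irgm1 at -0.67). The others were NF-kB targets (17, with Nfkbib at 0.37), cholesterol and fatty acid synthesis (23, with Mvd at 0.95), amino acid stress and transport (17, with Phgdh at 0.84) and the genes that flank Foxp3 on chromosome X (22, with Hdac6 at 0.69). DESeq2's 8 calls in them included Junb, Irgm1, Mvd, Phgdh, Pfkl, Nfkbib and mt-Nd4. Camera called none of the 10 lists, with adjusted p from 0.724 to 0.989. Mixed fry gave an adjusted p of 0.00082 for NF-kB targets and 0.00277 for cholesterol and fatty acid synthesis. It gave 0.00343 for amino acid stress and transport and 0.00413 for the genes flanking Foxp3. The rest of the 10 did not pass it.

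All 8 B cell markers tested had negative log2 fold changes, with a median of -0.71 and a mean of -1.46. The median was -1.31 without scurfy library 2 and -1.13 without wild-type library 1, and a filter at a mean of 50 left too few members for a test. Camera gave an adjusted p of 0.0117, with an adjusted p of 0.241 with an estimated correlation. The MHC class II gene H2-Aa fell from 71.7 ± 13.6 to 6.82 ± 8.08 normalized counts (log2 fold change -3.97, adjusted p = 0.0164, and 0.0706 without wild-type library 3). In limma H2-Ab1 (-3.48) and H2-Eb1 (-2.34) passed only adjusted over the list alone, which gave 3 genes in all, and Cd74 was at -0.99. Over all genes edgeR and voom each called 2 of the 8 markers lower, and DESeq2 called 1. The immunoglobulin and B cell receptor genes Ighm (10309 ± 744 in scurfy and 10862 ± 400 in wild type) did not pass, nor did Ighd (log2 fold change -0.17, SE 0.22) and Cd79b (-0.25, SE 0.23). Among lists too small for a set test, Cst3 rose by 0.59 of 3 myeloid markers (adjusted p = 0.0815 without wild-type library 2) and Car2 fell by 1.12 of 2 erythroid markers (0.0645 without wild-type library 3), each also called adjusted over the list alone. With the length trend removed Cst3 was at 0.33 and lost its call (adjusted p = 0.1695), while Car2 kept its call (0.0217). None of 3 CD4 T cell markers (Tnfrsf4 at 0.30) or of 4 sex-linked genes (Eif2s3y at -0.35) was called by limma, DESeq2, edgeR or voom, with 0 and 1 at an unadjusted p under 0.05. No marker of natural killer cells had a row.

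The authors' deposited table lists 891 genes with an adjusted p under 0.05, 415 higher and 476 lower, and 510 of the 518 limma calls were among them, all in the same direction. In the authors' deposited table the log2 fold change of Slc15a2 is -3.21. In data simulated for this comparison limma recovered 25.4% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 87.9% of those changed 4-fold. So differences below 2-fold were often not detectable with 3 libraries per group. False calls made up 8.06%. The simulation drew genes independently and held no shift by gene length between the groups, so that share need not hold for these libraries.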

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

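As refits of the whole comparison, the length and GC corrections and edgeR's test were chosen only after the data were seen. The separate tests of length and GC trends for the oxidative phosphorylation and cytosolic ribosomal protein lists had criteria written down before their results were seen. The count of 518 genes (246 higher, 272 lower) stayed within 1.5 times under both pseudocounts, TMM, upper-quartile and recomputed size factors, both stricter filters, voom and edgeR (493 to 623). On library size alone 929 genes passed, 761 of them lower. DESeq2 on the recovered reads gave 891 (415 higher, 476 lower). With the length trend removed 245 passed (82 higher, 163 lower), and with the GC trend removed 133 were lower. Leaving out 1 library gave 113 to 403 genes, 76 to 180 higher and 37 to 223 lower, with fewer samples by construction; for the other settings the cause was not tested. With the replicate block 372 passed (176 higher, 196 lower). Residuals of scurfy and wild-type libraries of the same number correlated at -0.03, -0.07 and -0.15, none of them positive. Libraries of different numbers were not set beside them, so whether the numbers pair these samples cannot be told. No named gene that was called changed sign in any setting run. Of these, 16 of the 50 called named genes kept an adjusted p under 0.05 in all settings run on them, Slc15a2 (adjusted p at most 0.00458), Dapl1 (at most 0.0124), S1pr1, Cd28, Cd3d, Cst7, Capg, Cox6b1, Uqcrh, Cox7a2 and Cox6c among them. For lists, oxidative phosphorylation lost its call with the length trend removed (median 0.11, adjusted p = 0.172) and kept it in the other refits, and cytosolic ribosomal proteins kept theirs in all refits (adjusted p at most 0.00347). B cell markers lost it at 20 reads in 3 libraries (6 members, median -0.34, adjusted p = 0.184). All 3 had an adjusted p of 0.241 with an estimated correlation. On library size alone the medians were 0.13 for oxidative phosphorylation and 0.21 for cytosolic ribosomal proteins, still above 0. With 3 libraries per group, limma found 25.4% of genes simulated at a 1.5-fold change.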

Other observations

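The gene families in this paragraph and the next were chosen by symbol only after the values were seen. The single genes named in both paragraphs were also chosen after their values were seen. Splicing factors of the Hnrnp and Srsf families were lower in scurfy cells as a set: 25 of 31 members had a negative log2 fold change, and 4 fell (Hnrnpk by 0.69, Hnrnpul1 by 0.79, Hnrnpf by 0.49 and Srsf6 by 0.44). None rose, with a median of -0.34 and a camera adjusted p of 1.76e-08 over 11 families (adjusted p = 0.095 with an estimated correlation). Their median length is 2939 bases, close to that of all genes, and with the length trend removed the median was -0.36 and the camera adjusted p 2.91e-07. The splicing kinase Clk1, which phosphorylates Srsf proteins, fell from 3056 ± 68.9 to 1784 ± 201 normalized counts (SD, n = 3). Of 28 ubiquitin-conjugating enzymes, 3 fell, Ube2d3 (-0.58), Ube2d1 (-0.70) and Ube2q1 (-0.43), with a median of -0.25 and a camera adjusted p of 0.00067 (adjusted p = 0.095 with an estimated correlation, 0.0036 for camera with the length trend removed).

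In the other direction, 132 of 150 ribosomal protein pseudogenes had a positive log2 fold change, 21 rose and 1 fell, with a median of 0.56 that was 0.17 with the length trend removed. Of 77 mitochondrial ribosomal proteins 5 rose and 1 fell, with a median of 0.12 that became -0.01 with the length trend removed. Proteasome subunits had a median of 0.15 (2 of 37 rose, Psmb7 among them by 1.16) that was 0.10 with the length trend removed (camera adjusted p = 0.0576). Lsm and Snrp proteins had a median of 0.27 (3 of 24 rose and 1 fell) that was 0.15 with the length trend removed (camera adjusted p = 0.076). The oligosaccharyltransferase subunit Dad1 rose from 2295 ± 342 to 4785 ± 228 normalized counts. Gm26917, a ribosomal RNA-like transcript, fell by 1.00 on the log2 scale, from 19417 ± 2331 to 9690 ± 1090. Together with Gm23935 and Mir6236 it took 0.0754% to 0.0946% of reads in scurfy libraries and 0.167% to 0.219% in wild-type libraries.

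Among the tests of patterns below, the trend with mean expression among genes that are not ribosomal proteins and the interval for Slc15a2 were chosen only after the results were seen. The trend with GC content was planned and run, then left out of the weighing after its results were seen: with it removed the medians were 0.27 (interval 0.09 to 0.35) for oxidative phosphorylation and 0.34 (0.19 to 0.47) for cytosolic ribosomal proteins. The higher oxidative phosphorylation list (median log2 fold change 0.27, bootstrap 95% interval 0.09 to 0.34) runs with gene length: after a length trend fitted on other genes was subtracted, the median was 0.11 with an interval of -0.08 to 0.23, and 6 members passed as higher against 11. The median stayed above 0 after a trend with mean expression was removed (0.24, interval 0.04 to 0.34) and without scurfy library 3 (0.24, 0.10 to 0.36). All these intervals resample the members of a list, so they do not measure the spread between libraries. A general excess of short transcripts in the scurfy libraries, from RNA quality, library preparation or the cells themselves, is consistent with the list as a whole, and the genotype and any such difference between libraries cannot be separated here. Cox6b1, Uqcrh, Cox7a2 and Cox6c kept adjusted p values of 0.0217 to 0.0316 with a length trend fitted on all genes removed, at lower log2 fold changes of 0.60, 0.64, 0.96 and 1.00, and 1 member of the list passed as lower.

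The higher cytosolic ribosomal protein list (median 0.35, interval 0.22 to 0.48) was lowered by the length correction to a median of 0.17 (interval 0.05 to 0.33). After it 2 members passed as higher against 7. The interval treats the members as independent, while their estimated correlation was 0.125. Whether length accounts for part of it or the whole therefore cannot be told. Subtracting a trend with mean expression gave 0.13 (interval -0.00 to 0.35), but that trend was fitted partly on 213 other genes with Rpl or Rps symbols, and fitted without them it left 0.27 (interval 0.14 to 0.43). Without scurfy library 3 the median was 0.35 (0.26 to 0.42). Reads shared with pseudogenes, which rose as well, were not tested and remain open beside a difference between the genotypes.

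Slc15a2 fell from 550 to 59.3 normalized counts in scurfy libraries, and a stretch of chromosome carried along from another strain was tested as a source. The 59 tested genes within 5 Mb on either side had a median absolute log2 fold change of 0.24, at percentile 49.9 of 10400 windows of as many neighbouring genes, and 2 of them passed the threshold. The percentile itself met, narrowly, the bound of at most 50 set beforehand for excluding a segment. Resampling the neighbours, added afterwards, gave percentiles from 7.94 to 77.0, which spans that bound and stays under the 95 set for a segment. So a segment remains open, as do a variant in Slc15a2 alone and an effect of the Foxp3 genotype on it, which were not tested.

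Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many as 518 genes, the real one. The highest of the others in limma was 0 genes, with 180 to 474 genes at an unadjusted p under 0.05 in them against 2456 in the real split. With 10 splits no share under 0.05 can be reached.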
